A study of Drosophila melanogaster with 20 samples.

How the data were processed

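RNA sequencing libraries from brain and fat body of female Oregon-R flies on normal food (ND) or on a high sugar diet for 5 days (HSD) were taken as deposited, with 20 libraries in 4 groups of 5. All libraries, on either diet, were listed at an age of 5 days and 5 days on the diet. The libraries were of poly(A) RNA and uniquely mapped reads were kept, per the labels. Reads were aligned with TopHat to the dm3 assembly, per the submitters' processing notes, which give no versions. The deposited values are RPKM per gene, per the labels. Each table held 15080 gene entries. The values were turned back into reads by finding a total per library and a length per gene that make them whole, and 99.85% of the values above 0 came out whole within 0.01 of a read. These recovered reads gave the depth per library, and the RPKM that 3 reads on a 1 kb gene would give was taken as the floor. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. 188 symbols that named several entries (1107 entries, at most 0.189% of reads) were left out, and 13973 genes were used. 5 symbols that read as dates were kept as they stand. No pair of tables held identical values (0 found). No coordinates are given because the tables use dm3 and the reference at hand is of another assembly, used for names only.

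Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(RPKM + 1), with trend, over genes with a mean RPKM of at least 1 over the libraries in the fit. Fold changes are on this log2(RPKM + 1) scale, which understates the change of low genes. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Principal components were taken per tissue from the same log2 values, centred per gene. The diet was tested in each tissue apart, the diet by tissue interaction in a fit of all 20 libraries, and brain against fat body on the 10 ND libraries. The comparisons, 33 gene lists, the named genes and most alternatives were chosen before the data were examined. Nothing in the labels says that replicates are separate animals or cohorts, so p-values measure the spread between these samples, which may be technical.

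The 33 lists held 670 entries, of which 600 were found in the tables and 70 were not. Matching older symbols, run as an alternative, found 58 entries, some of them already in the list under the older symbol (Col4a1 as Cg25C). Of the lists past the threshold, only lipolysis in the fat body lost its call with this matching. Of 15 starch digestion entries, 4 were found without it. The lists covered the insulin pathway, adipokinetic hormone and sugar sensing, glycolysis, pentose phosphate, gluconeogenesis, fat synthesis, lipolysis, starch digestion, antimicrobial peptides, Turandot peptides, heat shock, detoxification, endoplasmic reticulum stress, respiration, ribosomal proteins, ribosome biogenesis, neuropeptides, their receptors, biogenic amines, gustatory receptors, the clock, and markers of neuron, glia, eye, antenna, fat body, oenocyte, muscle, gut, ovary, Malpighian tubule, hemocyte and male reproductive tissue. Lists with at least 3 members past the filter were tested with camera at a preset correlation of 0.01, with 31 lists tested in each tissue. Camera with an estimated correlation, fry, and an exact permutation of list means over the 252 ways to split 10 libraries 5 against 5 were run beside it. The smallest p this permutation can give is 0.00794. It sets aside the pairing described below, and swaps of the diets within the 5 pairs, run as well, cannot give a p below 0.0625.

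Genes are named by a rule. For each diet comparison it takes the 12 largest changes per direction past the threshold with a mean RPKM of at least 5 and all 5 libraries of 1 diet beyond the mean of the other, and, where none passes, the 10 genes with the smallest unadjusted p. It adds up to 4 members per list with the smallest p and fixed hormone and metabolic genes whatever their values. For the tissues it takes the 5 largest differences per direction and marker genes, and for the interaction the 10 largest past the threshold. The text gives only some of the list members the rule names, and a member of the ribosome biogenesis list is not reported.

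The replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means, between diets. These were 0.44, 0.58, 0.55, 0.3 and 0.66 in the brain and 0.25, 0.15, 0.65, 0.23 and 0.13 in the fat body, each above 0.1, so same-numbered ND and HSD libraries were treated as pairs in the fit with a replicate block. Same-numbered libraries were each other's best-correlated partner only for number 5 in the brain and numbers 3 and 4 in the fat body. The labels give no source for the pairing, which is an assumption. Between tissues the correlations were -0.08, -0.23, 0.07, -0.04 and 0.07, so libraries of the 2 tissues were not paired.

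The gene fits were tested on simulated data drawn from the real means with 200 genes changed by known folds. Genes were drawn independently of each other, without pairs and without the split of brain libraries 4 and 5 from 1 to 3. Camera was run on simulated lists in the fat body design, and the other steps were not simulated. Recovered shares of genes changed 1.5-, 2-, 4- and 8-fold were 63.3%, 87.8%, 96.0% and 98.0% for the brain comparison (8882 genes), 4.2%, 28.0%, 70.2% and 91.5% for the fat body (8181 genes), 26.0%, 55.1%, 77.6% and 97.9% for the tissues (9199 genes) and 8.0%, 38.0%, 65.3% and 81.2% for the interaction (9275 genes). False calls were 8 of 179, 5 of 97, 9 of 134 and 16 of 110. In the simulated brain 7.74% of unchanged genes had an unadjusted p under 0.05 in limma, where the real comparison gave 79 of 8911 genes. The recovered shares may therefore not hold for the real brain comparison. Alternatives changed the pseudocount (0.1 and 5), the filter (none, and a mean RPKM of at least 5), the scaling (median-ratio and quantile), the block, array weights, robust fitting, the p criterion and the libraries in the fit. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.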

Results

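The transcriptomes of brain and fat body, the insect counterpart of liver and adipose tissue, were compared by RNA sequencing between female Oregon-R flies kept for 5 days on a high sugar diet (HSD) and flies kept on normal food (ND). Each of the 4 groups (brain ND, brain HSD, fat body ND and fat body HSD) held 5 libraries. Age and time on the diet were listed as 5 days for every library, those on normal food included. The values were RPKM per gene. The brain libraries of flies on normal food held 21.7, 24.8, 35.6, 37.7 and 35.9 M reads on genes for libraries 1 to 5, and those of flies on high sugar held 31, 32.1, 22.6, 39.1 and 46.3 M reads. The fat body libraries held 20, 30.8, 21, 5.6 and 40.4 M reads on normal food and 16.0, 10.7, 16.6, 11.1 and 23.4 M reads on high sugar. A count of 3 reads on a gene of 1 kb corresponded to an RPKM of 0.065 to 0.138 in the brain and 0.074 to 0.536 in the fat body, which covers counting error only. In the brain the first principal component held 64.6% of the variance and set libraries 4 and 5 of both diets apart from libraries 1 to 3. The first component of the fat body libraries held 37.6% and did not follow that division, since it set ND libraries 1, 2 and 5 and HSD libraries 1 and 5 (-40.3 to -18.9) apart from the other 5 (5.1 to 51.1). Diet values were therefore also computed within libraries 1 to 3 and within libraries 4 and 5, called batches here for both tissues. They are given for the gene lists past a threshold and for fixed genes whose sign differed. Fat body libraries ND 4, ND 5 and HSD 4 had 324, 101 and 414 genes with 1 to 3 reads, and the other fat body libraries 1105 or more. HSD 5 stood apart in its yolk protein share (13.65%, other HSD libraries 5.86% to 7.36%). Fat body values within libraries 4 and 5 therefore rest on libraries flagged below. Of the named genes tested, 30 of 133 in the fat body and 33 of 145 in the brain had opposite signs in the batches.

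To determine how high sugar changed the fat body, which stores and releases sugar and fat, HSD and ND libraries were compared gene by gene and over gene lists. Genes of the ribosome stood higher on high sugar. Genes of glycolysis, the pentose phosphate pathway and starch digestion stood lower, as did the fat body marker list and the ovary and eggshell list, by a list test with a preset correlation. These list calls were lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p 0.069 for each, 0.534 for ribosome biogenesis), and within libraries 4 and 5 the medians of the lower lists lay between -0.14 and 0.05 and that of ribosome biogenesis was -0.05. Among single genes, the insulin antagonist ImpL2, the lipid-binding protein gene Npc2h and the activin-like ligand gene daw had higher means, and the glucosidase gene tobi and the odorant-binding protein gene Obp99a had lower means. None of the 8224 genes passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, while 785 had an unadjusted p under 0.05 (639 higher and 146 lower). That excess of higher genes depended on the scaling. After median-ratio rescaling 341 genes had an unadjusted p under 0.05 (126 higher and 215 lower), of which 269 were among the 785, and after quantile normalization 459 had (237 and 222), of which 371 were. limma-voom on recovered reads gave 0 genes past the threshold and 296 at an unadjusted p under 0.05 (83 higher and 213 lower). The median gene stood 0.19 (log2) higher on high sugar, and changes are given relative to this shift where libraries were rescaled. Within libraries 1 to 3, 16 genes passed in limma (1490 at an unadjusted p under 0.05), and within libraries 4 and 5, 0 passed in limma (97 at an unadjusted p under 0.05).

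The 10 fat body genes with the smallest p did not pass the threshold (limma, Benjamini-Hochberg adjusted p 0.159 for each). CG3699 had an RPKM of 327 ± 166 (SD, n = 5) on normal food and 67.2 ± 34 (n = 5) on high sugar, a log2 fold change of -2.24 ± 0.37 (SE). Obp99a stood at 925 ± 478 and 227 ± 78.7, with a log2 fold change of -1.91 ± 0.34. ImpL2 stood at 45.0 ± 6.8 on normal food and 94.6 ± 25.5 on high sugar, with a log2 fold change of 1.03 ± 0.19. Npc2h stood at 345 ± 35.5 and 524 ± 44.5, and the ribosome assembly gene CG8801 (Non1) at 531 ± 87.9 and 934 ± 157. The cold shock protein gene yps stood at 118 ± 24.6 and 221 ± 36, and RpL23A at 2857 ± 174 and 4047 ± 342. CG8369 stood at 115 ± 21.3 and 56.7 ± 13.9. CG9510 and CG9515, which hold identical values and so cannot be told apart, stood at 146 ± 55.8 and 56.1 ± 15. Each of these log2 fold changes kept its sign within libraries 1 to 3 and within libraries 4 and 5. ImpL2, for example, stood at 1.22 and 0.74, and CG3699 at -3.03 and -1.05. Median-ratio rescaling kept the signs and moved Npc2h from 0.61 to 0.38 and RpL23A from 0.50 to 0.27.

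**Figure D1:**
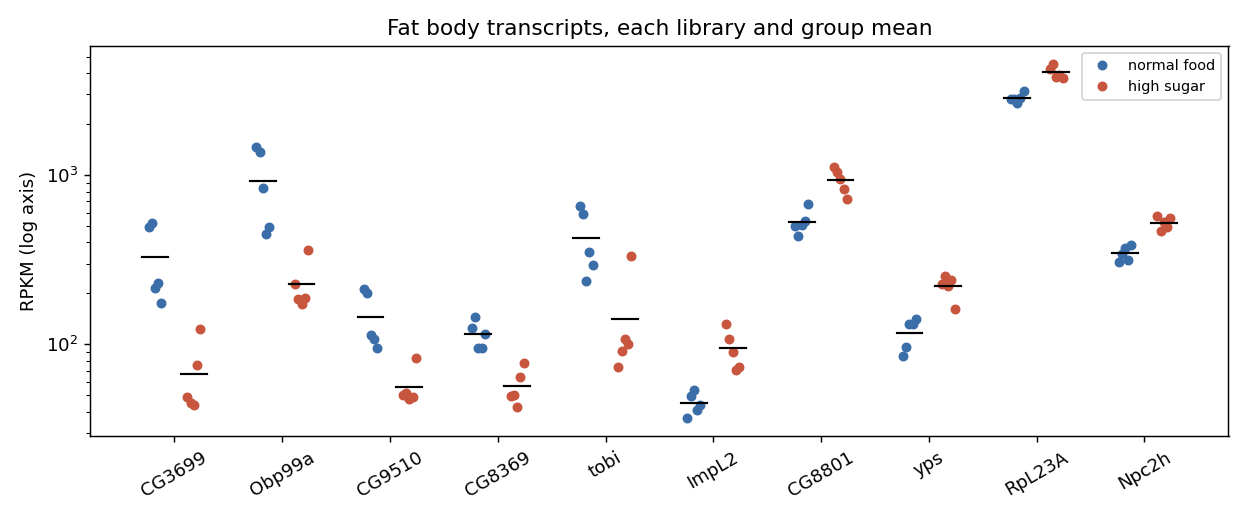
RPKM in each fat body library on normal food and on high sugar for named genes, on a log axis, with bars at the means of 5 libraries per diet. ImpL2 stood at 45.0 ± 6.8 on normal food and 94.6 ± 25.5 on high sugar, and none of the genes passed an adjusted p of 0.05 in limma (785 genes at an unadjusted p under 0.05, limma-voom 0 genes).

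Of the hormone and metabolic genes fixed in advance, none passed the threshold in the fat body (limma, Benjamini-Hochberg). The insulin-like peptide gene Ilp6 stood at 31.3 ± 15.3 on normal food and 46.1 ± 14.8 on high sugar, with a log2 fold change of 0.62 ± 0.33 that stood at 1.23 within libraries 1 to 3 and -0.31 within libraries 4 and 5. The adipokinetic hormone receptor gene GRHR (AkhR) stood at 73.0 ± 28.3 and 110 ± 8.5, a log2 fold change of 0.67 ± 0.23. The sugar-responsive factor sug stood at 90.7 ± 28.6 and 136 ± 22.7, a log2 fold change of 0.63 ± 0.23. The lipase gene bmm stood at 114 ± 23.3 and 80.1 ± 13.1, a log2 fold change of -0.50 ± 0.16. tobi stood at 428 ± 187 and 141 ± 107, a log2 fold change of -1.72 ± 0.40, and Pepck stood at 797 ± 516 and 472 ± 283. InR, Thor and foxo had log2 fold changes of 0.28, 0.24 and 0.17, and after median-ratio rescaling 0.10, 0.01 and -0.06. Rescaling also moved Ilp6 to 0.40, GRHR to 0.44 and sug to 0.40. In libraries 1 to 3 and libraries 4 and 5, InR stood at 0.56 and -0.12 and Thor at -0.11 and 0.76. The fatty acid synthesis genes CG3523 (FASN1) and CG11198 (ACC) had log2 fold changes of -0.20 and -0.29, and -0.43 and -0.52 after rescaling. Leucokinin had a log2 fold change of 0.99 ± 0.48 and its fat body RPKM was low (2.24 and 5.42). The tachykinin receptor gene Takr99D had a log2 fold change of -0.17, with -1.28 and 1.5 within the batches and -0.35 after rescaling. Ilp2 was listed at 0 in all fat body libraries, and Ilp3, Ilp5, Akh, Lkr and Tk lay below the expression filter.

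Of 31 gene lists tested in the fat body, 12 passed in camera with the preset correlation (limma, Benjamini-Hochberg adjusted p under 0.05), 0 passed with an estimated correlation and 0 with exact permutation of the list means, where 7 lists had an unadjusted exact p under 0.05. Transcripts of cytosolic ribosomal proteins had a median log2 fold change of 0.42, and 81 of 83 members had a higher mean (limma camera, Benjamini-Hochberg adjusted p 2.58e-40; with an estimated correlation 0.069). The list mean lay above the highest ND library in 5 of 5 HSD libraries, with a two-sided exact permutation p of 0.00794, the smallest that 5 against 5 libraries can give, and 0.205 after adjustment over the lists. That permutation sets aside the pairing of the libraries. Swapping the diets within pairs gave an exact permutation p of 0.0625, the smallest that 5 pairs can give, so no list could pass 0.05 that way. The median stood at 0.54 within libraries 1 to 3 and at 0.25 within libraries 4 and 5, and at 0.19 after median-ratio rescaling. Of its members 71 passed in limma when adjusted over the list alone and 0 over all genes tested. RpL13, RpL24 and RpS4 had log2 fold changes of 0.49, 0.49 and 0.48, and 0.26, 0.26 and 0.25 after rescaling. In fry, which tests whether the list moves without setting it against other genes, this list had an adjusted p of 0.031 and was the only list past the threshold.

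The ribosome biogenesis list had a median of 0.56 with 16 of 16 members higher (limma camera, Benjamini-Hochberg adjusted p 5.2e-04; with an estimated correlation 0.534). Its members Fib and RpI135 had log2 fold changes of 0.67 and 0.61, and 0.44 and 0.42 after rescaling. The list stood at 0.34 after rescaling, at 0.36 without ND library 1 and 0.35 without HSD library 2, and at 0.90 within libraries 1 to 3 and -0.05 within libraries 4 and 5, and 1 member passed when adjusted over the list alone. The glycolysis list had a median of -0.28 with 11 of 13 members lower (adjusted p 1.44e-09 in limma camera with Benjamini-Hochberg; with an estimated correlation 0.069). PyK, Pgi, Eno and Gapdh2 had log2 fold changes of -0.33, -0.55, -0.31 and -0.28, and -0.56, -0.78, -0.54 and -0.51 after rescaling. The median was -0.39 within libraries 1 to 3 and -0.05 within libraries 4 and 5, and -0.51 after median-ratio rescaling. The pentose phosphate and NADPH list had a median of -0.20 with 6 of 7 members lower (adjusted p 3.69e-06; with an estimated correlation 0.069), -0.35 and -0.12 within the batches and -0.43 after rescaling. Its member Men stood at 876 on normal food and 526 on high sugar. Starch and sugar digestion genes had a median of -0.51 over 3 members (adjusted p 9.45e-05; with an estimated correlation 0.069), of which tobi passed when adjusted over the list alone. The median moved to -0.72 with rescaling, -0.80 without ND library 5, -0.77 without HSD library 4 and -1.39 without ND 4, ND 5 and HSD 4 together. Amy-d and Amy-p had log2 fold changes of -0.46 and -0.51 but stood at 0.05 and 0.91 within libraries 4 and 5, where the list median was 0.05.

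The fat body marker list had a median of -0.42 (limma camera, Benjamini-Hochberg adjusted p 1.21e-10; with an estimated correlation 0.069), with 1 member higher and 6 lower when adjusted over the list alone. It stood at -0.30 and -0.14 within the batches, at -0.65 after rescaling and at -0.16 without libraries ND 4, ND 5 and HSD 4 together. The yolk protein genes Yp1, Yp2 and Yp3 had log2 fold changes of -0.97, -1.43 and -1.12, which were -0.14, -1.04 and -0.24 after quantile normalization and -0.13, -0.14 and -0.21 within libraries 4 and 5. After median-ratio rescaling they were -1.2, -1.66 and -1.35. The storage protein gene Lsp2 had a log2 fold change of -4.54 ± 0.94, from 161 ± 162 to 5.64 ± 8.6. Cyp4g1 moved the other way, with a log2 fold change of 0.67 (0.44 after median-ratio rescaling and 0.98 after quantile normalization). The share of reads on Yp1, Yp2 and Yp3 was 17.4 ± 6.24% on normal food and 8.01 ± 3.21% on high sugar (two-sided exact permutation p 0.0238, adjusted over the 8 comparisons of library measures 0.0952). Swapping the diets within pairs gave an exact permutation p of 0.125. The share lay below the ND mean in 5 of 5 HSD libraries. Within libraries 1 to 3 the means were 21.5% and 6.35%, and within libraries 4 and 5 they were 11.2% and 10.5%. The ovary and eggshell list had a median of -1.60 with 22 of 24 members lower (limma camera, Benjamini-Hochberg adjusted p 1.53e-12; with an estimated correlation 0.069; exact permutation p 0.0952). Its median was -1.58 within libraries 1 to 3 and -0.10 within libraries 4 and 5, and it moved to -0.78 without ND library 1 and -0.98 without ND library 2. The chorion genes Cp15, Cp18 and Cp19 had log2 fold changes of -2.51, -3.54 and -4.81 and Vm32E one of -3.48.

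Antimicrobial peptide genes had a median near 0 (-0.05, 15 of 27 lower; limma camera with Benjamini-Hochberg adjusted p 4.26e-04; with an estimated correlation 0.534). They stood at -1.08 within libraries 1 to 3 and 0.67 within libraries 4 and 5, so that direction did not hold across the batches. The call was lost after median-ratio rescaling (-0.28, limma camera with Benjamini-Hochberg adjusted p 0.0673), quantile normalization (0.101) and limma-voom (0.31), and without ND library 2, where the median turned to 0.18 (0.927). With the call kept, the median turned to 0.10 and 0.01 without HSD libraries 2 and 4. It moved to -0.30 without ND library 5, -0.34 without HSD library 5 and -0.43 without ND 4, ND 5 and HSD 4 together. PGRP-SD, PGRP-SB1 and Def had log2 fold changes of -0.86, -0.98 and -1.77, and IM23 one of 1.5. Within the batches PGRP-SB1 stood at -2.03 and 0.61. The detoxification list (-0.06; adjusted p 8.72e-04, with an estimated correlation 0.069) and the gluconeogenesis, glycogen and trehalose list (-0.08; adjusted p 1.28e-03, with an estimated correlation 0.069) had 11 of 22 and 7 of 12 members lower. Rescaling moved these medians to -0.26 and -0.31. Within the batches detoxification stood at 0.08 and -0.17 and gluconeogenesis at -0.12 and -0.01. The calls held with 1 library left out, but the detoxification median turned to 0.05 without ND library 4 and 0.03 without HSD library 4, and the gluconeogenesis median to 0.03 without ND library 5 and 0.02 without HSD library 2. In the called direction, detoxification moved to -0.15 without HSD library 2 and -0.12 without ND library 1. Gluconeogenesis moved to -0.23, -0.16 and -0.14 without HSD library 5, ND library 1 and ND library 3. Cyp28d1 stood at 299 and 174, and UGP and CG10924 had log2 fold changes of -0.51 and -0.88, of which CG10924 stood at -1.91 and 0.68 within the batches. Turandot peptides had a median of -0.31 over 4 members (adjusted p 0.0215; with an estimated correlation 0.442), -0.19 and -0.59 within the batches and -0.54 after rescaling. Without HSD library 2 the median turned to 0.10 and the call was lost (limma camera, Benjamini-Hochberg adjusted p 0.283), and it was lost without ND library 4 (-0.09, 0.0542) or ND library 5 (-0.13, 0.182). It moved to -0.53, -0.50 and -0.48 without ND library 1, HSD library 3 and HSD library 4, and to 0.06 (0.441) without ND 4, ND 5 and HSD 4 together. TotM stood at 265 and 146. Lipolysis and fatty acid oxidation genes had a median of -0.03 with 7 of 13 lower (adjusted p 0.0328; with an estimated correlation 0.342), 0.01 and -0.05 within the batches and -0.26 after rescaling, and this call held in 3 of 10 fits with 1 library left out. The median turned to 0.02, 0.02 and 0.04 without ND library 1, ND library 4 and HSD library 4. CG3902 had a log2 fold change of -0.77.

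The remaining fat body lists did not pass on the deposited values with all libraries (limma camera, Benjamini-Hochberg). The insulin pathway list had a median of 0.24 (adjusted p 0.128), which rescaling moved to 0.02, and ImpL2 passed when adjusted over the list alone. S6k and chico had log2 fold changes of 0.48 and 0.50, and 0.25 and 0.28 after rescaling. The adipokinetic hormone and sugar sensing list had a median of 0.13 (adjusted p 0.834) and -0.07 after rescaling, with 3 members higher and 1 lower when adjusted over the list alone. Of these members daw stood at 27.4 and 52.6 and bigmax had a log2 fold change of 0.53 (0.30 after rescaling). Fatty acid synthesis and fat storage genes had a median of 0.03 (adjusted p 0.071), mitochondrial respiration genes 0.11 (0.321), heat shock proteins -0.08 (0.793) and endoplasmic reticulum and ATF4 stress genes 0.12 (0.172). After median-ratio rescaling these medians were -0.19, -0.12, -0.27 and -0.11, and fatty acid synthesis then passed (adjusted p 0.0104; with an estimated correlation 0.765). Hsc70-4, a heat shock cognate, stood at 1366 and 2148. Feeding and metabolic neuropeptides had a median of 0.37 (0.985), neuropeptide receptors 0.13 (0.816), biogenic amine genes 0.27 (0.985) and circadian clock genes 0.06 (0.816). Among tissue markers, medians were 0.12 for neuron (0.969), -0.03 for glia (0.273), 0.30 for oenocyte (0.128), 0.35 for muscle (0.163), 1.25 for gut (0.132), 0.44 for Malpighian tubule (0.834), 0.17 for hemocyte (0.952) and -0.16 for male reproductive genes (0.842). Antenna markers had a median of 0.70 while their mean was -0.11 and camera gave a lower direction (0.102). Gut markers passed after rescaling (limma camera, Benjamini-Hochberg adjusted p 0.00229; with an estimated correlation 0.485). With 1 library left out, fatty acid synthesis, muscle, oenocyte, gut, antenna, endoplasmic reticulum stress and mitochondrial respiration genes passed in at least 1 of the 10 fits. Rescaling turned the medians of neuropeptide receptors (-0.05), clock genes (-0.16), neuron markers (-0.05) and hemocyte markers (-0.03), and limma-voom that of male reproductive genes (0.16). The sugar and gustatory receptor list was not tested because fewer than 3 members were expressed.

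**Figure D2:**
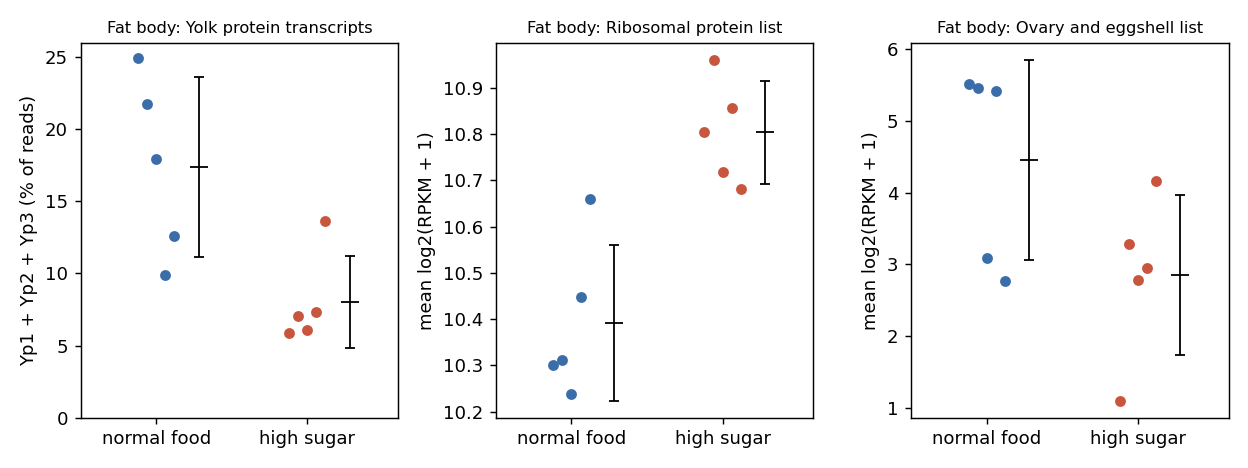
Share of reads on Yp1, Yp2 and Yp3 (percent) and mean log2(RPKM + 1) of the ribosomal protein and of the ovary and eggshell lists in each fat body library, with the mean and SD of 5 libraries per diet. For cytosolic ribosomal proteins, 5 of 5 HSD libraries lay above the highest ND library as deposited, and median-ratio rescaling reduced the median log2 fold change from 0.42 to 0.19.

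To determine whether the diet also changed the brain, which holds the insulin-producing neurons and the neuropeptide systems of feeding, the brain libraries were compared in the same way. Antimicrobial peptide genes had lower means on high sugar, as did hemocyte and fat body marker genes, by a list test with a preset correlation. These calls were lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p 0.599, 0.599 and 0.822), and the medians lay farther from 0 in libraries 4 and 5 than in libraries 1 to 3. Libraries 4 and 5 carried unequal median shares of the fat body level (2.65% and 5.63% on normal food, 3.94% and 1.94% on high sugar). The calls therefore cannot by themselves tell a change in the brain from carried tissue. With the fat body marker mean as a covariate the antimicrobial and hemocyte calls were kept at the preset correlation. Neuropeptide, receptor, neuron and glia genes had medians within 0.02 of 0. None of the 8911 genes passed (limma, Benjamini-Hochberg), with a smallest adjusted p of 1, and 79 had an unadjusted p under 0.05 (66 higher and 13 lower). A share of 0.05 of the genes tested would be 446. Of the 16 splits of these libraries that part all pairs, the real one included, 10 gave at least 79 genes, and the highest other gave 291. limma-voom gave 0 genes and 82 at an unadjusted p under 0.05. The median gene stood at 0.02. Within libraries 1 to 3 there were 0 genes past the threshold in limma and 283 at an unadjusted p under 0.05, and within libraries 4 and 5 there were 0 and 115.

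The brain insulin-like peptide genes Ilp2, Ilp3 and Ilp5 had lower means on high sugar, none past the threshold (adjusted p 1 in limma with Benjamini-Hochberg). Ilp2 stood at 385 ± 90.8 (SD, n = 5) on normal food and 317 ± 27.6 on high sugar, a log2 fold change of -0.26 ± 0.14 (SE). Ilp3 stood at 44.7 ± 16.2 and 36.0 ± 2.52, a log2 fold change of -0.24 ± 0.21. Ilp5 stood at 100 ± 51.7 and 66.2 ± 11.2, a log2 fold change of -0.49 ± 0.26, with 1 ND library at 190. In libraries 1 to 3 and libraries 4 and 5, Ilp2 stood at -0.21 and -0.33, Ilp3 at -0.05 and -0.52 and Ilp5 at -0.12 and -1.03. Leucokinin stood at 23.1 ± 7.24 and 18.1 ± 0.932, a log2 fold change of -0.29 ± 0.16. Its receptor gene Lkr had a log2 fold change of -0.07. Tk stood at 143 and 148, and Takr99D had a log2 fold change of 0.02. Akh stood at 113 ± 152 and 62.8 ± 74.8 with a log2 fold change of 0.05 ± 1.78, and at 0.75 and -1 within the batches. Ilp6, whose mean was not lower (13.58 and 13.61), InR, foxo and Thor had log2 fold changes of 0.02, 0.04, 0.08 and -0.03, and within the batches Ilp6 stood at 0.13 and -0.15, InR at -0.02 and 0.13 and Thor at -0.25 and 0.30. Tk stood at 0.10 and -0.05 and Takr99D at -0.01 and 0.07. GRHR, sug, Pepck, CG3523, CG11198 and bmm had log2 fold changes of 0.11, 0.09, -0.03, -0.09, -0.07 and -0.13, and tobi one of -0.67 ± 1.03. Within the batches CG3523 stood at 0.04 and -0.28, CG11198 at 0.01 and -0.20 and tobi at 0.21 and -1.98.

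The 10 brain genes with the smallest p had small changes and did not pass (limma, Benjamini-Hochberg adjusted p 1). CG3812 (Agpat1) stood at 20.2 ± 1.13 (n = 5) on normal food and 23 ± 0.628 (n = 5) on high sugar, a log2 fold change of 0.18 ± 0.05. The small RNA gene snmRNA:400 stood at 10.3 ± 2.4 and 6.89 ± 1.45, a log2 fold change of -0.51 ± 0.17. CG3542 (Prp40), MAN1, egg, msl-3, CG7442 and CG13197 had log2 fold changes of 0.16, 0.14, 0.12, 0.12, 0.14 and 0.11. CG33785 and CG33786, which hold identical values, had a log2 fold change of 0.23 ± 0.08.

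Of 31 brain lists, 8 passed in camera with the preset correlation (limma, Benjamini-Hochberg), 0 with an estimated correlation, 0 in fry and 0 in exact permutation, and 14 with the replicate number as a block, of which 0 held in that fit with an estimated correlation. In each of the 8 lists 0 members passed, whether adjusted over the list alone or over all genes tested. Antimicrobial peptide genes had a median of -0.70 with 26 of 26 members lower (adjusted p 4.64e-14; with an estimated correlation 0.599). The median was 0.05 within libraries 1 to 3 and -1.67 within libraries 4 and 5. CecA2, CecB, CecC and PGRP-LB had log2 fold changes of -1.17, -0.94, -0.87 and -0.53. CecC stood at 0.12 and -2.35 within the batches. The list median was -0.28 without ND library 4 and -0.45 without HSD library 3. Hemocyte markers had a median of -0.26 with 9 of 9 lower (adjusted p 7.05e-05; with an estimated correlation 0.599), and -0.09 (adjusted p 0.016) and -0.49 (1.07e-12) within the batches. Without ND library 5 the call was lost (-0.05, limma camera with Benjamini-Hochberg adjusted p 0.121), and without ND library 4 the median was -0.17. Fat body markers had a median of -0.49 with 13 of 14 lower (adjusted p 9.67e-05; with an estimated correlation 0.822), and -0.01 and -0.74 within the batches. This call was lost without ND library 5 (0.03, adjusted p 0.331) and without ND library 4 (-0.14, 0.109), and the median was -0.77 without ND library 3 and -0.25 without HSD library 3. Cytosolic ribosomal proteins had a median of -0.05 with 79 of 83 lower (adjusted p 3.08e-05; with an estimated correlation 0.822), which became 0.10 without ND library 5 (adjusted p 0.00505, the other direction) and 0.00 without HSD library 1 (0.105). It stood at -0.06 and -0.05 within the batches.

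The detoxification, heat shock, endoplasmic reticulum and ATF4 stress, and pentose phosphate lists had brain medians of -0.05, -0.11, -0.08 and -0.13, with 17 of 20, 9 of 12, 10 of 12 and 7 of 7 members lower. Their adjusted p in limma camera with Benjamini-Hochberg was 4.81e-03, 5.93e-03, 0.0188 and 0.0465, and 0.822 for each with an estimated correlation. Without ND library 5 these medians were 0.08, -0.05, 0.05 and 0.07 and all 4 calls were lost. Calls were also lost without ND library 4 (heat shock -0.05, endoplasmic reticulum stress -0.09, pentose phosphate -0.06), HSD library 1 (detoxification 0.01, endoplasmic reticulum stress -0.05, pentose phosphate -0.04), HSD library 2 (-0.02, -0.03, -0.03 and -0.07 for the 4 lists) and HSD library 3 (pentose phosphate -0.09), while heat shock stood at -0.17 without ND library 2 or HSD library 5. In libraries 1 to 3 these 4 lists stood at -0.02, -0.04, -0.02 and -0.03, and in libraries 4 and 5 at -0.10, -0.16, -0.16 and -0.27. With the fat body marker mean as a covariate the medians were 0.04, -0.01, 0.03 and 0.09 and all 4 calls were lost (limma camera, Benjamini-Hochberg adjusted p 0.911, 0.197, 0.911 and 0.421). The other 23 brain lists did not pass on the deposited values with all libraries and no block, and 14 of them passed in at least 1 fit with 1 library left out. After median-ratio rescaling eye, gut and fatty acid synthesis genes passed (limma camera, Benjamini-Hochberg adjusted p 0.00916, 0.0162 and 0.0354; with an estimated correlation 0.74 for each) and pentose phosphate was lost (0.0658). With the replicate block, eye (adjusted p 0.00924), antenna (0.026), gut (0.0335), fatty acid synthesis (0.0351), lipolysis (0.0351) and male reproductive genes (0.0351) passed, and with an estimated correlation in that fit 0 lists passed (adjusted p 0.496 or more for these). Medians were 0.01 for the insulin pathway (adjusted p 0.535), 0.01 for adipokinetic hormone and sugar sensing (0.344), 0.00 for glycolysis (0.633), -0.03 for gluconeogenesis, glycogen and trehalose (0.239), -0.03 for fatty acid synthesis (0.0557) and -0.02 for lipolysis (0.0776). Ribosome biogenesis genes had a median of 0.05 (0.0776), mitochondrial respiration genes 0.02 (0.713), neuropeptides 0.02 (0.189), neuropeptide receptors 0.01 (0.762), biogenic amine genes 0.02 (0.762) and clock genes 0.01 (0.762). Glia markers had a median of 0.02 (0.618), as did neuron markers (0.762), whose mean was -0.01. The glial transporter gene CG1732 (Gat) stood at 191 and 211. Turandot peptides had a median of 0.31 (0.618), antenna markers -0.14 (0.0566), oenocyte markers -0.04 (0.162), muscle markers 0.00 (0.192), ovary markers -0.01 (0.192) and male reproductive markers -0.14 (0.0557). Starch digestion genes had a median of 0.54 while camera gave a lower direction (0.762), and without HSD library 4 the median was -0.79 and the list passed (limma camera, Benjamini-Hochberg adjusted p 0.00817). Eye markers had a median of 0.55 (0.0502), with -0.14 and 1.85 within the batches, and gut markers one of 0.97 (0.0505). The gut value rested on HSD library 4, with a list mean of 5.03 against 0.01 to 0.12 in the other HSD libraries.

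**Figure D3:**
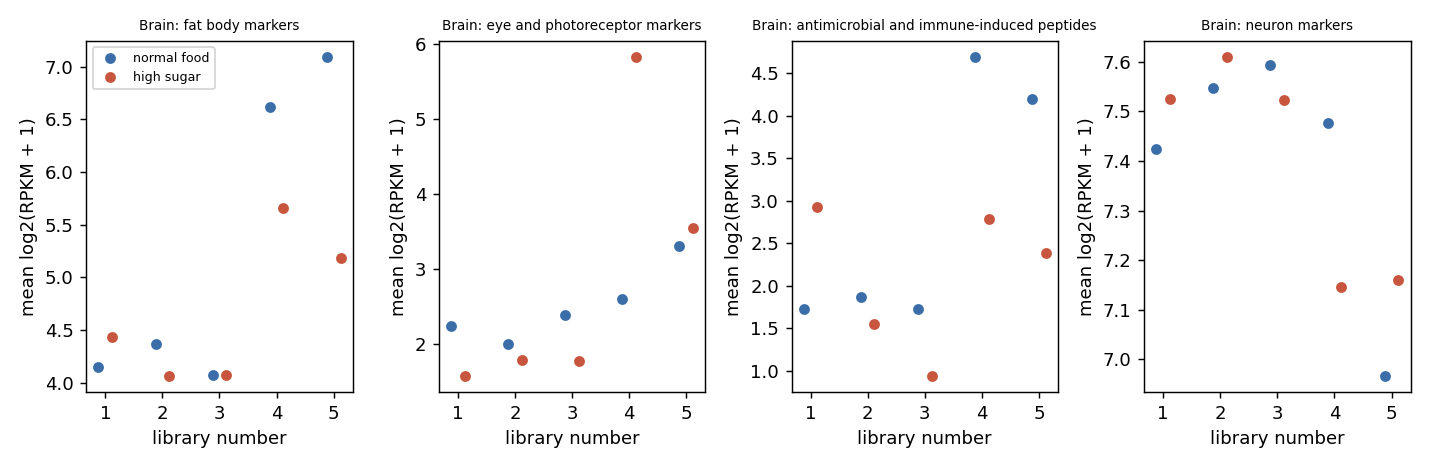
Mean log2(RPKM + 1) of 4 gene lists in each brain library, drawn by library number for flies on normal food and on high sugar. The fat body marker list lay between 4.06 and 4.43 in libraries 1 to 3 and between 5.18 and 7.09 in libraries 4 and 5 of both diets.

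Whether the diet acted differently in fat body and brain was tested as an interaction over all 20 libraries. Ribosomal protein and ribosome biogenesis genes had the more positive diet effect in the fat body, and glycolysis and eggshell genes the more negative, by a list test with a preset correlation. These calls were lost with an estimated correlation (limma camera, Benjamini-Hochberg adjusted p 0.682, 0.682, 0.329 and 0.176) and by permutation of the list means (adjusted p 0.518, 0.736, 0.736 and 0.736). None of the 9281 genes passed (limma, Benjamini-Hochberg, smallest adjusted p 0.772), while 598 had an unadjusted p under 0.05 (535 with a more positive effect in the fat body and 63 with a more negative effect). The median gene stood at 0.16, which bears on this split. Across the 7470 genes tested in both tissues, the log2 fold changes had a Pearson r of 0.20 (jackknife SE 0.22 over the libraries) and a Spearman rho of 0.13 (0.21). This relation is across genes, which are not independent replicates. No gene passed the threshold in either tissue in limma. Of the genes at an unadjusted p under 0.05, 5 were higher in both tissues, where 4.92 would be shared by independent lists (Fisher's exact p 1), and 0 were lower in both, where 0.184 would be.

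Brain and fat body on normal food were compared to check the tissue labels and describe the tissues. Neuron markers were higher in the brain for 15 of 15 genes, with a median of -6.76 (log2, fat body over brain), and glia markers for 8 of 9, with a median of -3.54 (limma, Benjamini-Hochberg). Fat body markers were higher in the fat body for 11 of 15 genes, with a median of 3.93. Oenocyte markers were higher in the fat body for 5 of 6 genes and ovary and eggshell markers for 17 of 24. In all, 6896 of 9220 genes passed, 2140 higher in the fat body and 4756 higher in the brain. Because the median gene stood at -0.61, the share of passing genes higher in the fat body was 31% as deposited and 42.8% after median-ratio rescaling. Cyp4g1 stood at 27.8 in the brain and 8800 in the fat body (log2 fold change 11.47 ± 1.19, limma adjusted p 4.2e-06). Its brain mean rested on ND library 4, at 138, and without that library the log2 fold change was 12.84. Brain ND libraries 4 and 5 carried fat body transcripts, as the plot of brain gene lists shows. Oenocyte markers, Cyp4g1 among them, stood apart in ND library 4 only (mean log2 4.52, other ND libraries 2.65 to 2.74). CG16926, Fad2, CG34291 and CG16904 followed, with log2 fold changes of 9.12, 8.98, 8.52 and 8.29. Gad1 stood at 508 in the brain and 0.121 in the fat body, and miple at 596 and 0.347. Obp44a, CG14989 and CG10186 had log2 fold changes of -10.98, -9.17 and -8.92.

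Other markers in the same comparison were Syt1 and repo, with log2 fold changes of -8.58 and -5, and Yp1 and osk, with 6.59 and 6.48. Lsp2 was not past the threshold (limma, Benjamini-Hochberg adjusted p 0.2), but passed without brain ND library 5 (0.0416) and within libraries 1 to 3 (7.08e-05). Eye markers were higher in the brain for 11 of 12 genes, with a median of -2.97. Muscle markers had a median of 2.66 with 12 genes higher in the fat body and 3 higher in the brain, and gut markers one of 1.88 with 5 genes higher in the fat body. Antenna markers split into 2 higher and 2 lower, with a median of 0.05. Malpighian tubule markers had a median of -4.66 over 2 genes, hemocyte markers one of -0.36 and male reproductive markers one of -0.38.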

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

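Tests chosen only after the result was seen were the diet as source of the brain libraries' split, the reads freed in the fat body, the depth of 3 fat body libraries, the counts over other splits of the libraries between the diets within a tissue, and the fits on the sides of the fat body's first principal component. In groups of 5 libraries, 28 of 248 values lay apart from the nearest of the other 4 by more than 0.71 of the group's range. A share of 0.05 would be 12.4 for independent, normally distributed values. These values share libraries and include the identical CG9510 and CG9515, so the excess cannot be read as an excess over chance.

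In the brain, ND library 5 stood apart for glycolysis (mean log2 7.5, others 7 to 7.1), detoxification (5.83, others 4.96 to 5.20), ribosomal proteins (9.27, others 8.41 to 8.57), biogenic amines (4.85, others 4.99 to 5.04) and neuron markers (6.97, others 7.42 to 7.59). It also stood apart in RPKM for CG3812 (18.2, others 20.2 to 21), Ilp5 (190, others 66.4 to 96.3), Thor (38.5, others 8.04 to 15.6) and Pepck (32.8, others 1.11 to 5.23). ND library 4 stood apart for oenocyte markers (4.52, others 2.65 to 2.74). HSD library 4 stood apart for starch digestion (5.99, others 0.59 to 1.98) and gut markers (5.03, others 0.01 to 0.12). HSD library 5 had 1438 genes with 1 to 3 reads (others 1352 to 1369).

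Brain libraries 4 and 5 of both diets carried fat body and eye transcripts. The split ran within both diets, which the diet alone does not explain: 4 of the 4 libraries had a fat body marker mean above each of libraries 1 to 3 of their own diet, which restates the pattern as first seen. Fat body tissue carried into the dissection may be the source. Of 50 chosen genes, at least 76% lay within 4-fold of 1 common share of their fat body level in each of the 4 libraries. In libraries 1 to 3 at most 70% did. These genes were the most abundant of those far higher in the fat body than in the brain on normal food, ovary markers left out. The brain mean in that choice held ND libraries 4 and 5, which limits the shares these genes can show there. That comparison with libraries 1 to 3 was added after a first run, and subtracting their level gave 72% or more. The median share was 1.94% to 5.63% of the fat body level, against 0.241% to 0.44%, and eye markers, lower in the fat body than in the brain by a median of -2.97 (log2), need another source that was not tested. Oenocyte markers did not follow the share. Among ND libraries they stood apart in library 4 only (4.52, others 2.65 to 2.74), while its share was 2.65% and that of library 5 was 5.63%.

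In the fat body, ND library 2 stood apart for glycolysis (7.96, others 7.77 to 7.81), ND library 5 for hemocyte markers (4.69, others 4.17 to 4.31) and ND library 1 for Pepck (RPKM 1710, others 472 to 715). HSD library 1 stood apart for oenocyte markers (7.31, others 6.47 to 6.68). HSD library 5 stood apart for the yolk protein share (13.65%, others 5.86% to 7.36%), the insulin pathway (4.33, others 4.55 to 4.63), antimicrobial peptides (7.39, others 4.63 to 5.33), and in RPKM for Obp99a (363, others 172 to 226), CG9510 and CG9515 (82.9 each, others 47.4 to 51.5), bmm (103, others 72.0 to 76.3) and tobi (332, others 73.4 to 108). HSD library 4 stood apart for genes above 0 (8657, others 10871 to 11345), genes with 1 to 3 reads (414, others 1131 to 1243) and male reproductive markers (1.75, others 2.68 to 3.01).

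Fat body libraries ND 4, ND 5 and HSD 4 had few genes with 1 to 3 reads. Depth alone is argued against, since thinned to 4 M reads the highest of the 3 had 9502 genes with reads and the lowest of the other 7 had 9729. Few starting molecules amplified to many reads may be the source, since genes with 50 to 200 expected reads scattered by 0.77 or more (log2) in the 3 libraries and by at most 0.75 in the other 7, a narrow margin. These libraries fall in both diets, and no biological explanation was tested.

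Ribosomal protein transcripts stood higher in the fat body on high sugar. Libraries ND 4, ND 5 and HSD 4 are argued against as the source, since without them the list mean differed by 0.51 (two-sided exact permutation p 0.0286, the smallest that 35 splits can give). Reads freed by lower yolk protein transcripts stay open: set against each library's median gene the difference was 0.20 (exact permutation p 0.341), and with yolk protein reads taken out of the total it was 0.25 (exact permutation p 0.0159), against 0.41 as deposited. Ovary carried into the dissection may contribute and cannot be told apart from the diet, because the ovary markers are themselves lower on high sugar. With their mean as a covariate the list kept its camera call (median 0.37, limma adjusted p 8.22e-54), while 0 members passed in limma adjusted over the list alone (71 without the covariate). That call uses the preset correlation, and without the covariate it was lost with an estimated correlation (limma camera adjusted p 0.069). An effect of the diet itself stays open as well.

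For 11 lists the diet effect differed between fat body and brain in limma camera on the interaction with the preset correlation (Benjamini-Hochberg). Medians were 0.48 for ribosomal proteins (adjusted p 3.42e-23), 0.51 for ribosome biogenesis (7.08e-04), 0.47 for oenocyte markers (0.0275), -1.58 for ovary markers (1.18e-12), -0.26 for glycolysis (8.49e-09), -0.09 for pentose phosphate (0.0275), -0.04 for gluconeogenesis (0.0115), -1.05 for starch digestion (0.0275), -0.98 for Turandot peptides (0.0275), -0.56 for eye markers (5.27e-04) and -0.11 for fat body markers (0.0146). With an estimated correlation none passed in limma, with 0.176 for ovary markers, 0.329 for glycolysis, 0.789 for fat body markers and 0.682 for each of the other 8. In permutation of the list means none passed either, with adjusted p from 0.378 for oenocyte markers to 0.872.

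Other splits of the libraries were counted. Because same-numbered libraries were treated as pairs, each diet split was set against the 16 splits that part all 5 pairs. These are too few for a share under 0.05. In the brain the real split gave 0 genes in limma (highest other 0), 79 at an unadjusted p under 0.05 (highest other 291) and 8 lists (highest other 17). In the fat body it gave 0 genes in limma (highest other 0), 785 at an unadjusted p under 0.05 (highest other 1118), 12 lists (reached in 6 of the 16 splits, highest other 14) and 3138 genes with array weights (highest other 3838). The 84 other splits drawn keep some pairs together. They reached 3489 genes at an unadjusted p under 0.05 in the brain and 3255 in the fat body, and 1 of them gave 2456 genes past the threshold in the fat body, with ND libraries 1, 2 and 5 and HSD libraries 1 and 5 on the same side. These counts point to a structure of the samples other than the diet. That fat body split is the division along the first principal component (37.6% of the variance), and its sides differ in the level of the median gene (log2 3.23 to 3.6 against 3.88 to 4.11). After median-ratio rescaling the split gave 1582 genes in limma, and after quantile normalization 1049. The sides come from a component of these same genes, so many calls between them follow from that choice. These counts therefore cannot decide whether more than an overall shift is present. With the sides as a term the diet gave 0 genes in limma (910 at an unadjusted p under 0.05) and 9 lists. What set the sides apart stays open. For the interaction, chance was not excluded: 16 of 100 splits gave as many as the real 598 genes at an unadjusted p under 0.05 (highest other 1217). The count of 0 genes past the threshold in limma is reached by any split (100 of 100), so it says nothing about chance. Between tissues 1 of 100 splits, the real one, gave 6896 genes (highest other 0). Every other split puts both tissues on both sides, which widens the spread, so their counts say little about chance.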

How the results depend on the processing

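Settings added after the results were seen were limma-voom, the exact permutations of list means, over all splits and within pairs, and the fits within libraries 1 to 3 and within 4 and 5. Added as well were the library batch as a term, the marker covariates and the fit without fat body libraries ND 4, ND 5 and HSD 4. So were the sides of the fat body's first principal component as a term and the matching of older symbols. Quasi-likelihood and negative binomial tests on recovered reads with edgeR and DESeq2 were planned and not run, because the deposited values are RPKM and not counts; limma-voom was run on the recovered reads in their place.

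In the brain, 0 genes passed in limma under every fit run, leave-one-out included (0 to 0; limma-voom 0, 82 at an unadjusted p under 0.05). With an unadjusted p under 0.05, 79 genes passed, and 1 with an absolute log2 fold change above 1 as well. The 8 brain lists became 14 with the replicate block (0 of them with an estimated correlation in that fit), 0 with array weights, 4 within libraries 1 to 3, 13 with the library batch as a term, and 0 with an estimated correlation, 0 in fry and 0 in exact permutation over all splits or within pairs. The 4 lists within libraries 1 to 3 included eye markers, which were not among the 8. Leaving out 1 library gave 5 to 14 lists, with 5 without HSD 1, 13 without ND 1, 14 without ND 2 and 13 without HSD 4. The block changed no other call of the counts, and the cause of these moves was not tested.

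In the fat body, the 0 genes became 3138 with array weights (2824 higher and 314 lower), 16 within libraries 1 to 3, 41 with all 20 libraries in 1 fit, 785 at an unadjusted p under 0.05 and 96 with an absolute log2 fold change above 1 as well. Leaving out 1 library gave 0 to 19 genes, with 19 without HSD 5 (3 higher and 16 lower). CG3699, CG7686, CG8801, Lsp2, Obp99a, smp-30 and Yp3 were among both the 16 and the 19. The 12 fat body lists became 9 with the sides of the first component as a term (gluconeogenesis, lipolysis, antimicrobial and Turandot lists lost, muscle markers gained), 5 within libraries 4 and 5, 0 with an estimated correlation, 1 in fry and 0 in exact permutation over all splits or within pairs, and 10 to 15 with 1 library left out. The 5 lists within libraries 4 and 5 included mitochondrial respiration (median 0.14), not among the 12, and antimicrobial peptides in the other direction (0.67). The interaction gave 2103 genes with array weights (1955 more positive and 148 more negative) and 277 within libraries 1 to 3 (219 and 58). The cause was not tested. In fits with array weights limma warned that the estimation stopped before its convergence tolerance was reached. Array weights raise the influence of libraries close to the fitted means, and other splits gave as many calls with them.

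The direction of the list test reversed for these lists, and the cause was not tested. In the brain, leaving out 1 library gave medians of -0.19 to 0.07 for pentose phosphate, -0.13 to 0.08 for detoxification, -0.12 to 0.10 for ribosomal proteins, -0.02 to 0.07 for biogenic amines and -0.15 to 0.05 for endoplasmic reticulum stress, each reversed without ND 5. With the fat body marker mean as a covariate, pentose phosphate stood at 0.09, ribosomal proteins at 0.05, biogenic amines at -0.03, fat body markers at 0.08 and muscle markers at 0.34. For fat body markers the covariate is the list's own mean, so the loss of their change was fixed in advance. In the same fit detoxification (0.04), heat shock (-0.01) and endoplasmic reticulum stress (0.03) lost their calls. Eye markers stood at -0.14 within libraries 1 to 3. In the fat body, antimicrobial peptides stood at 0.67 within libraries 4 and 5 and at 0.37 with the ovary marker mean as a covariate. For other lists the median alone changed sign while the test kept its direction, as for detoxification in the fat body (0.08 within libraries 1 to 3), and starch digestion (0.05) and ribosome biogenesis (-0.05) within libraries 4 and 5, where neither passed. Between tissues, moody stood at 0.02 after median-ratio rescaling against -0.42 as deposited.

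Over single lists and alternatives, 650 values in the brain and 714 in the fat body kept direction and side of the threshold, 78 and 41 passed where the main value did not, and 70 and 83 no longer passed. Of the named genes, 116 values passed in the fat body under some alternative and 0 in the brain in limma (79 genes at an unadjusted p under 0.05, limma-voom 0).

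The counts between tissues kept within 1996 to 2215 and 4523 to 5137 with 1 library left out, and the relation of the tissues' diet changes within an r of 0.08 to 0.29 and a rho of 0.04 to 0.21. Fat body ND 4, with 5.6 M reads, had a floor of 0.536 RPKM for a 1 kb gene, so differences below this level were not detectable there.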

Other observations

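The translation gene lists were chosen after the ribosomal protein result was seen, and the proteasome and snoRNA lists with them; the time-of-day test was chosen before its result was seen. Whether other translation genes shared the fat body pattern was tested with 2 lists. Mitochondrial ribosomal protein genes were higher by 0.31 (two-sided exact permutation p 0.135, adjusted 0.135), with 66 of 72 members higher, and by 0.10 against the median gene of each library (exact permutation p 0.365). Translation initiation factor genes were higher by 0.38 (exact permutation p 0.0556, adjusted 0.0741), with 22 of 23 higher, and by 0.17 against the median gene (exact permutation p 0.0794). The tests leave open whether these genes moved beyond the shift of all genes. Proteasome subunit genes, run beside them, had a median of 0.36 with 27 of 27 higher and snoRNA genes one of 0.33 with 45 of 63 higher (exact permutation p 0.0556 for each).

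Sampling at another time of day was tested with the mean log2 of per, tim and vri minus that of Clk and cry. In the brain it differed by 0.07 between the diets (two-sided exact permutation p 0.77) against a mean SD of 0.37. That cannot decide on sampling time, since the index can take the same value at different times of day and its daily range was not estimated. In the fat body it differed by 0.32 (exact permutation p 0.27) against a mean SD of 0.42, which leaves the question open.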
